A study of Picochlorum sp. 'soloecismus' with 30 samples.

How the data were processed

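DNA methylation was measured by whole genome bisulfite sequencing in Picochlorum soloecismus, a single-celled green alga grown in shaken flasks with nitrate-supplied medium and a light and dark cycle. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that is still read as C counts as methylated; incomplete conversion and hydroxymethylation are read in the same way. The 30 libraries came from 2 arms, untreated control cultures and cultures given 20 µM 5-aza-2'-deoxycytidine (5AZA) each day, sampled on each of days 4 to 7 and on day 10, with 3 biological replicates for each arm and day. 5AZA is a cytidine analogue that is built into DNA and traps DNA methyltransferases. Aliquots were taken from the flasks daily, and the sources used here do not state whether a replicate number stands for the same flask on successive days, nor whether the untreated cultures received the solvent of the drug.

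Library preparation, sequencing and processing followed a commercial methylation sequencing service pipeline (Methyl-MaxiSeq, Zymo Research), per the labels' protocols. Bismark, Bowtie2 and MethylDackel were named per the submitters' processing notes; their versions, their settings and the genome build are not given in the sources used here. The authors deposited 15 tables, 1 for each day and each of 3 sequence contexts (CpG, CHG and CHH, where H is A, C or T), each with the 6 libraries of that day side by side. Per the file headers, each library has a methylation fraction per cytosine, which the authors gave to 2 decimals, and a count of total reads over that cytosine. The authors' deposited tables also hold a difference of fractions between the arms, a p-value per cytosine and a class (hypermethylated, hypomethylated or insignificant); the test behind that p-value is not given in the sources used here. In the values, the p-value was exactly 1 for every cytosine with a difference clearly below 10 percentage points, and every classed cytosine had a difference of at least 10 points in size. All per-sample columns were matched to a sample by the arm and replicate number in their headers. The headers of the day 7 columns carry a date in place of the day, so their day was taken from the table they stand in and from the dates in the headers of other days.

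Every listed cytosine had at least 5 reads in all 6 libraries of its day. The CHG and CHH tables of all days but day 7 (8 tables) each stop at exactly 1048575 cytosines, the number of data rows a spreadsheet can hold, so they cover only part of the genome; the CHG tables reach 36 or 37 of 38 scaffolds and the CHH tables reach 23 of them. The CpG tables and the day 7 tables do not have this length. Methylated reads were recovered as the fraction times the total reads, rounded to a whole number; for totals above 100 reads, which held for 5.28% to 45.0% of CpG sites per library, a fraction of 2 decimals leaves more than 1 possible count, and the rounding moved no library's CpG level by more than 0.0126 points.

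The level of a library is its methylated reads over all reads, summed over listed cytosines. Daily differences between arms were tested with an exact two-sided permutation test, which with 3 against 3 cannot give a p below 0.1. Differences over all days used 100000 permutations of the arm labels within each day, with a 95% interval from the same permutations; differences across the days of one arm used 100000 permutations of an F statistic, and treatment by day interactions used 100000 permutations of the residuals of the additive model. These 3 families used cytosines listed on all 5 days: 925058 CpG, 1013755 CHG (36 scaffolds) and 964025 CHH (23 scaffolds). All 3 treat the libraries of different days as independent. Benjamini-Hochberg adjustment was made within each family.

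Counts were summed in 1 kb windows with at least 5 listed cytosines and a pooled methylation of 2% to 98%. A quasi-binomial logistic model compared the arms, with the dispersion of each window moderated as in limma's squeezeVar, a floor of 1 on the dispersion, an F test and Benjamini-Hochberg adjustment at 0.05. The same model with day as a factor was fitted to all 30 libraries, with and without the interaction. The model without the day term was also fitted to single CpG sites of each day and to windows of day 10 against day 4 in controls. These designs, the alternatives and the rule for naming windows were fixed before the data were examined. The rule named, per day, the 5 windows with the largest rise and the 5 with the largest fall among those past the threshold without overlap of the arms, and over all days the 10 largest each way with 1 sign on all days. Since no window passed, windows and sites named below were chosen after their values were seen. Lists of genes by product name had also been fixed (DNA methylation, chromatin, lipid synthesis, starch and carbon, photosynthesis, nitrogen, cell cycle, mobile elements, translation), but no annotation or genome sequence was used here, so these lists were not run and regions are named by scaffold and 1-based position, without the prefix shared by all scaffold names.

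Added after the data were seen were the classes of CpG sites by pooled level, the clusters of methylated sites (sites at 50% or more, at most 50 bp apart, at least 2 per cluster), the correlation of site levels by distance (running mean over 11 bp), the level at sites of 70% or more, the relation of that level to the CHG level, and the variants that use clusters or fewer scaffolds, unweighted site means for windows, across days and for interactions, fewer libraries for interactions, the fit of single sites over all days, and leaving out 5AZA replicate 2 of day 4 alone over all days. The alternatives fixed with the designs were a coverage minimum of 10 reads, unweighted site means for the level differences between arms, 500 bp windows, no methylation filter, limma on log2 ratios of methylated to unmethylated reads with a pseudocount of 0.5, Fisher's exact test on summed counts, an added threshold of 10 points, a replicate block and leaving out each replicate for the other comparisons.

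The moderated dispersions were checked against limma's own function on the windows of each day, and the largest relative difference was 1.32e-15. For single sites of days 5, 6, 7 and 10, the moderation gave all sites of a day the same dispersion. A chi-square test then took the place of the F test, and a site's own spread between replicates did not enter its p-value. In simulated counts on the real depths with 200 changed windows among 12442 (day 10), 79% of changes of 5 points and all 200 changes of 10 points were called. For the same test on day 4, with 12517 windows, 64.5% of changes of 5 points were called. With all 30 libraries and 12468 windows, all 200 changes of 5 points were called. At single sites the power was lower: among 246534 sites of day 10, none of 200 changes of 10 points and 32% of 200 changes of 20 points were called. For the interaction, a change of 10 points on day 10 alone was called in 92.5% of 200 windows. Changed windows and sites were drawn only from intermediate pooled levels of 10% or more. These shares therefore do not cover windows under 10% or the sites with the highest levels. The simulations draw windows independently, whereas the real libraries also shift as a whole.

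Replicate libraries were compared for duplicates: over the 30 pairs of replicates within a group, the chi-square of window counts was 1.96 to 15.2 times its degrees of freedom, so no pair was as alike as sampling noise alone allows and each library was counted once. Read depths summed over listed sites were 46202241 to 100820951 per library for CpG, 46923799 to 105334530 for CHG and 38364810 to 193487772 for CHH. In these sums a read that covers several sites counts at each of them. Counting error is small at this depth: the library with the lowest CpG sum, 5AZA replicate 3 of day 10, had a CpG level of 11.605% with a 95% Wilson interval of 11.596% to 11.614%. Reads without molecular identifiers are not independent molecules, and calls at neighbouring sites can come from the same read. Such intervals therefore cover counting error only and may be too narrow for it. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9.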

Results

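The methylation of single cytosines was followed through the growth of Picochlorum soloecismus in 30 libraries, 3 from untreated control cultures and 3 from cultures given 20 µM of the DNA methyltransferase inhibitor 5AZA daily, at each of 5 sampling times (days 4 to 7 and day 10). Read depths summed over CpG sites were 46202241 to 100820951 per library. Between 940815 and 953051 CpG sites were listed per day, with a median depth of 42 to 93 reads per library. On day 7, the only day with complete tables in all contexts, 1230209 CHG and 3864026 CHH cytosines were listed. Median depth was 38 to 88 reads at CHG and 28 to 72 reads at CHH cytosines. The sites lay on 38 scaffolds that together reached 15.2 Mb.

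Methylation was found at CpG sites and was divided sharply between sites. On 36 scaffolds, 76.6% of 919131 CpG sites had a pooled level under 2%, 10.4% (95732 sites) had 70% or more, and only 4.57% lay between 30% and 70%. Sites of 70% or more had a mean level of 81.3% ± 2.10 (SD, n = 30 libraries). The 2 cytosines of a CG pair on opposite strands were methylated or unmethylated together: across 451600 pairs, Pearson's r was 0.990 (across sites, which are not independent replicates), and 1 pair had 70% or more on one strand and under 20% on the other. Their levels were not equal: in 60541 pairs with a mean of 50% or more, the strands differed by a median of 6.28 points, and by 10 points or more in 28.8% of the pairs. Among these 36 scaffolds, which leave out the 2 deepest (contig576 and contig569), the CpG level ran from 7.495% on contig559-543-547c to 16.6% on contig551. The longest scaffold, contig599 (1550939 bp), had a level of 12.1%.

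Methylated CpG sites stood in short groups at a regular distance from each other. The correlation between the levels of CpG sites on the 36 scaffolds reached a maximum of 0.773 at a distance of 177 bp, with further maxima of 0.530 at 355 bp, 0.341 at 533 bp and 0.217 at 710 bp. In between it fell below 0, to -0.164 at 90 bp and -0.166 at 260 bp. Of methylated sites (50% or more), 75.9% of the partners 177 bp away were also methylated, against 0.0946% of the partners 90 bp away. Grouping methylated sites at most 50 bp apart gave 34592 clusters, which held 98.1% of the methylated sites and had a median width of 5 bp. Of the spacings between neighbouring cluster centres, 47.9% were 150 to 200 bp and 15.7% were 300 to 400 bp.

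**Figure D1:**
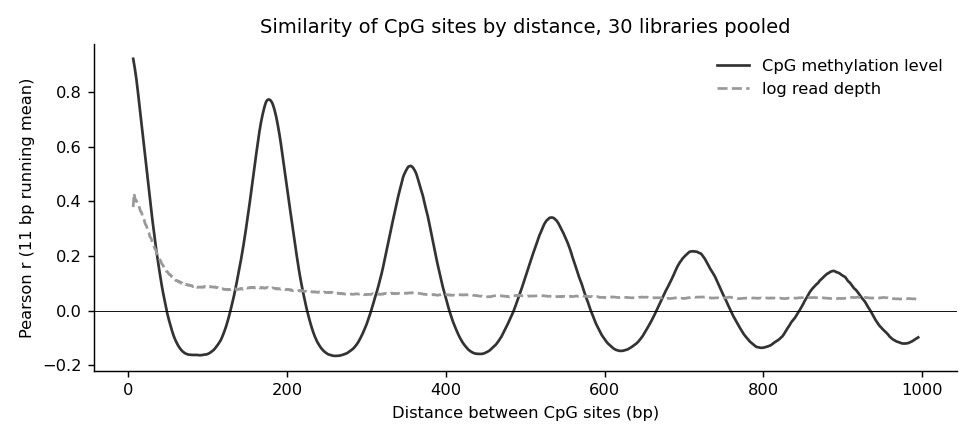
Pearson correlation (y axis, 11 bp running mean) between CpG sites separated by the distance on the x axis (bp), for the methylation level (solid line) and for the log of read depth (dashed line), 30 libraries pooled, 36 scaffolds. The methylation curve has maxima at 177, 355, 533 and 710 bp and lies below 0 between them, and the depth curve has no such maxima.

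The longest unbroken run of regularly spaced clusters was on contig592-558c-549c-548c-566, positions 184064 to 187850, with 22 clusters at a median spacing of 181.5 bp. Together with flanks of 400 bp, this stretch held 343 listed CpG sites, 81 of them at 50% or more and 248 under 10%. The 81 methylated sites had a mean level of 79.1% ± 2.19 in control and 79.0% ± 2.65 in 5AZA libraries (SD, n = 15 each). A run of 18 clusters lay on contig582, positions 60475 to 63392. Clusters were absent from other stretches, the longest being 18758 bp of contig581 (positions 7182 to 25939, 1223 CpG sites, level 1.72%) and 15002 bp of contig596-571c (positions 156007 to 171008, 863 CpG sites, level 0.959%). Among 14742 windows of 1 kb on the 36 scaffolds, 15.4% had a level under 2% and the median was 11.6%. The highest window was at 22001 to 23000 on contig564 with 70.6% over 10 sites, and 181 windows reached 40%.

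**Figure D2:**
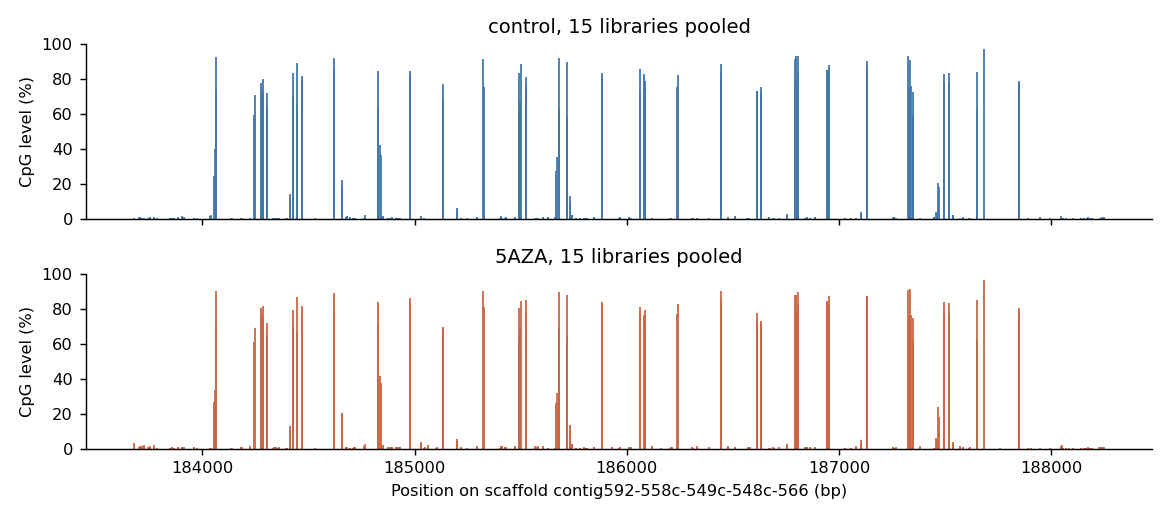
CpG methylation level (y axis, percent) by position (x axis, bp) on contig592-558c-549c-548c-566, with 1 vertical line per listed CpG site, in 15 control libraries (upper panel) and 15 5AZA libraries (lower panel), reads pooled. The 22 clusters between 184064 and 187850 stand at the same positions in both arms, with unmethylated sites between them.

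Outside CpG, the level was low in all libraries. The CHG level was 0.705% ± 0.245 and the CHH level 0.803% ± 0.250 (SD, n = 30). Inside the CpG clusters the mean non-CG level was slightly below that outside. The CHG level inside clusters minus that outside was -0.00658 ± 0.0131 points, and for CHH it was -0.0169 ± 0.0239 points (SD, n = 30). Outside here means more than 30 bp from any cluster and not on the 2 deepest scaffolds. The level inside was the higher one in 8 of 30 libraries for CHG and in 7 for CHH. The 2 deepest scaffolds, contig576 (72464 bp, 5.51 times the median scaffold depth) and contig569 (38646 bp, 4.54 times), had CpG levels of 0.790% and 0.729%, in the range of the non-CG contexts. In control libraries, contig576 had 5.81 ± 0.513 times the median site depth of the other scaffolds, and 5.49 ± 0.967 times in 5AZA libraries (SD, n = 15 each; permutation p = 0.246, adjusted p = 0.549 over 3 library measures).

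The first question of the design is whether 5AZA changed the methylation level on a given day. The CpG level was close to 12% in both arms on every day. It was 11.9% ± 0.180 in control and 12.04% ± 0.558 in 5AZA cultures on day 4, 12.3% ± 0.197 and 12.2% ± 0.406 on day 5, and 12.1% ± 0.180 and 11.9% ± 0.207 on day 6 (SD, n = 3 each). On day 7 the levels were 11.6% ± 0.337 and 11.7% ± 0.215, and on day 10 they were 11.4% ± 0.396 and 11.98% ± 0.334 (SD, n = 3 each). The 5AZA minus control differences were 0.147, -0.128, -0.291, 0.119 and 0.619 points in the order of the days. Exact permutation p-values were 0.8, 0.9, 0.2, 0.6 and 0.2, and the smallest p the design allows is 0.1. The sign turned when 1 library was left out: without 5AZA replicate 3 the day 4 difference was -0.133 points, without 5AZA replicate 2 that of day 5 was 0.0856 points, and without control replicate 2 or 5AZA replicate 3 that of day 7 was -0.0566 or -0.00454 points. With an unweighted mean of site fractions the differences were 0.0236, -0.0191, -0.118, -0.133 and 0.346 points in the order of the days, and without control replicate 2 that of day 10 was 0.403 points.

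**Figure D3:**
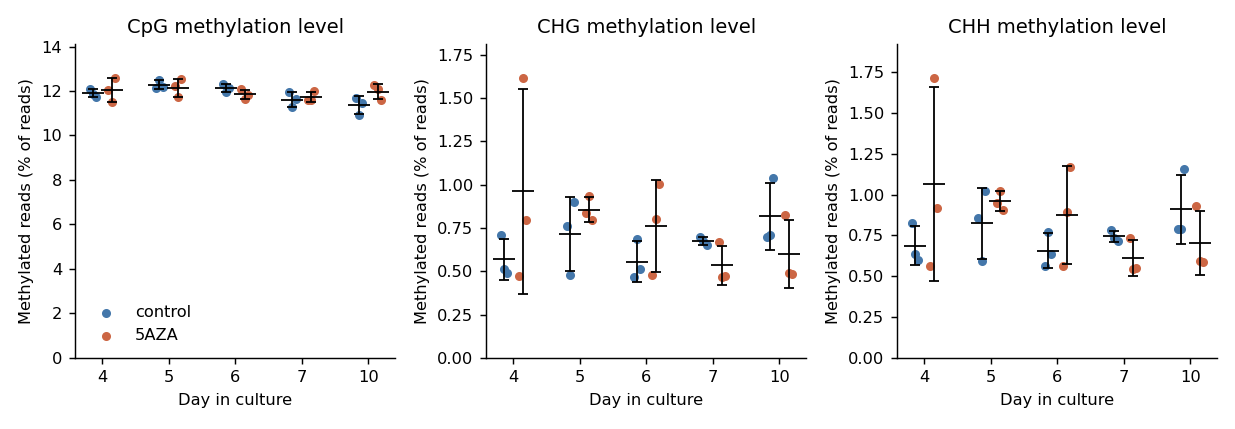
Methylation level (y axis, percent of reads called methylated, from 0) by day in culture (x axis) in CpG, CHG and CHH context, for control (blue) and 5AZA (orange) libraries. Points are libraries, and black bars are the mean and SD of 3 libraries. The CpG level stays near 12% in both arms, and 5AZA replicate 2 of day 4 has the highest CHG (1.62%) and CHH (1.72%) levels.

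In the non-CG contexts the 5AZA libraries had higher means on days 4 to 6 and lower means on days 7 and 10, with the arms overlapping on each day. The CHG level on day 4 was 0.570% ± 0.119 in control and 0.962% ± 0.592 in 5AZA libraries (SD, n = 3 each), and 5AZA replicate 2 alone stood at 1.62%. Without that library the CHG difference on day 4 was 0.0630 points in place of 0.392. On day 10 the CHG level was 0.817% ± 0.194 in control and 0.600% ± 0.196 in 5AZA libraries (SD, n = 3 each), and without control replicate 3 (1.04%) the difference was -0.105 points in place of -0.217. Exact permutation p-values over the 5 days were 0.2 to 0.4 for CHG and 0.3 to 0.4 for CHH. CHG and CHH tables other than those of day 7 list only part of the genome.

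Over all 5 days the arms did not differ by more than the spread between libraries. The CpG level was 11.9% ± 0.418 in control and 11.97% ± 0.340 in 5AZA libraries (SD, n = 15 each), a difference of 0.0979 points with a 95% interval of -0.152 to 0.351 (permutation p = 0.434, adjusted p = 0.466). For CHG the difference was 0.0751 points (interval -0.104 to 0.264, permutation p = 0.466), and for CHH it was 0.0776 points (interval -0.106 to 0.268, permutation p = 0.448); both had an adjusted p of 0.466. CpG losses beyond the lower bound of -0.152 points lie outside the interval, which treats the libraries of different days as independent. If the same flasks were sampled on several days, the interval may be too narrow. The difference of the CpG level was 0.0106 points without replicate 3 and 0.0188 with an unweighted mean of site fractions. Without 5AZA replicate 2 of day 4, a choice made after seeing the data, it was 0.150. Without replicate 2 the CHG and CHH differences turned to -0.0114 and -0.00852 points. A treatment by day interaction of the level was not detected in CpG (F = 1.74, permutation p = 0.182), CHG (F = 1.61, permutation p = 0.201) or CHH (F = 1.48, permutation p = 0.240), with an adjusted p of 0.240 for all 3 contexts. Without replicate 1 the CHG interaction had F = 3.48 (permutation p = 0.0491, adjusted p = 0.0841). The CHH interaction then had F = 3.37 (permutation p = 0.0561, adjusted p = 0.0841). Without replicate 3 the F was 0.597 for CHG and 0.538 for CHH.

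The second question is how methylation moved through the growth cycle. In control cultures the mean CpG level, over sites listed on all days, was 11.9% ± 0.178 on day 4, 12.3% ± 0.195 on day 5, 12.2% ± 0.180 on day 6, 11.6% ± 0.336 on day 7 and 11.4% ± 0.396 on day 10 (SD, n = 3 each). The range of these means was 0.920 points (permutation p = 0.0108, adjusted p = 0.0646 over 6 tests), so the change across days in controls did not pass the adjustment. With an unweighted mean of site fractions, chosen after seeing the data, the range was 0.613 points and passed (permutation p = 0.00366, adjusted p = 0.0220), while for the read-weighted level without replicate 2 or replicate 3 the unadjusted permutation p was 0.0617 or 0.145. In 5AZA cultures the day means spanned 0.420 points, from 12.2% ± 0.400 on day 5 to 11.7% ± 0.217 on day 7 (SD, n = 3 each; permutation p = 0.632, adjusted p = 0.632). Day 10 minus day 4 was -0.541 points in controls (exact p = 0.1, the smallest possible, adjusted p = 0.8) and -0.0919 points in 5AZA cultures (exact p = 1, adjusted p = 1). CHG and CHH levels across days had adjusted permutation p-values of 0.553 in both arms.

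The 95732 sites of 70% or more were picked by the level pooled over all 30 libraries, 5AZA libraries included. A site with a large loss under 5AZA could thus fall below 70% and be left out. At these sites the mean level of the controls was 82.4% ± 0.0368 on day 4, 82.2% ± 1.92 on day 5, 82.7% ± 0.732 on day 6, 81.9% ± 0.847 on day 7 and 78.9% ± 2.11 on day 10 (SD, n = 3 each). The 5AZA libraries had 79.7% ± 4.58, 81.3% ± 3.06, 80.5% ± 1.54, 81.5% ± 0.399 and 82.1% ± 0.619 on the same days (SD, n = 3 each). On day 4 the 5AZA minus control difference of -2.76 points rested on 5AZA replicate 2 (74.4%), and without that library it was -0.115 points. On day 5 the difference of -0.878 points turned to 0.226 without control replicate 2 and to 0.506 without 5AZA replicate 2. Day 10 was the only day without overlap, with all 3 5AZA libraries above all 3 controls by a mean of 3.16 points (exact p = 0.1, the smallest possible; adjusted p = 0.5 over 5 days). The CHG level, to which the level at these sites was related across libraries, also differed on that day, by -0.217 points. Over the 5 days the difference was -0.627 points (interval -2.27 to 0.996, permutation p = 0.465), and it turned to 0.411 points without replicate 2. Across days the controls had a range of 3.83 points (permutation p = 0.0412, adjusted p = 0.247 over 6 tests), which was past an unadjusted 0.05 only with all replicates, since leaving out replicate 1, 2 or 3 gave permutation p-values of 0.0970, 0.0718 and 0.285.

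**Figure D4:**
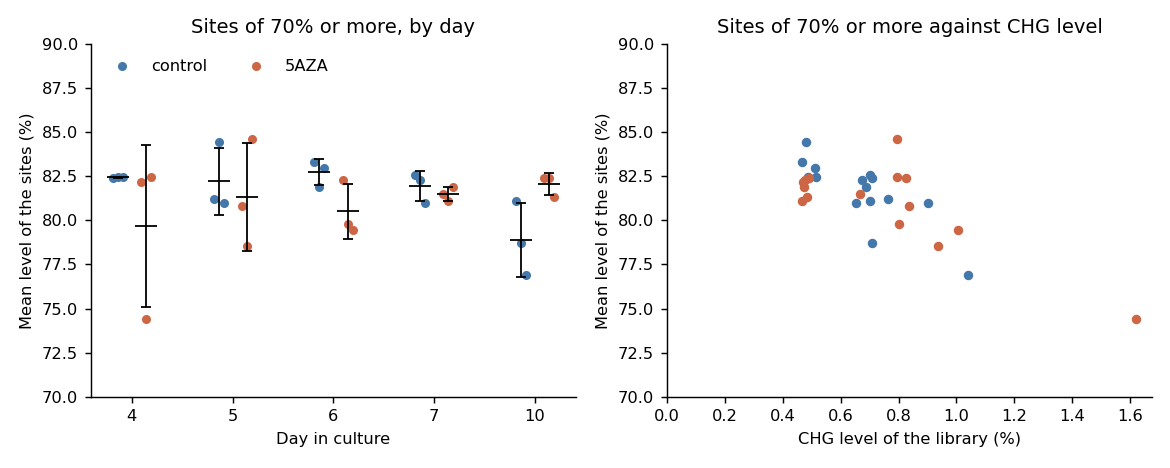
Mean level of the 95732 CpG sites with a pooled level of 70% or more (y axes, percent, shown from 70 to 90), by day in culture (left; points are libraries, bars the mean and SD of 3) and against the CHG level of the same library in percent (right), for control (blue) and 5AZA (orange) libraries. The lowest library is 5AZA replicate 2 of day 4, at 74.4% with a CHG level of 1.62%, and the control libraries of day 10 lie below the 5AZA libraries of that day.

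Single regions were then compared between the arms. None of the 1 kb CpG windows passed the threshold, out of 12517, 12555, 12447, 12320 and 12442 tested in the order of the days. Among windows in which the libraries of the arms did not overlap, the largest fall on day 4 was at 611001 to 612000 on contig595, with 52.3% ± 1.54 in control and 44.4% ± 6.69 in 5AZA libraries (SD, n = 3 each, adjusted p = 0.528). The corresponding window on day 5, at 18001 to 19000 on contig554, had 34.4% ± 4.39 and 25.1% ± 2.14 (SD, n = 3 each, adjusted p = 1.00), and no tested window differed by 10 points or more on any day. The largest rise without overlap on day 4 was at 1325001 to 1326000 on contig596-571c, with 10.4% ± 1.79 and 16.8% ± 3.75 (SD, n = 3 each, adjusted p = 0.630). On day 6 the window at 745001 to 746000 on contig595 had 40.7% ± 1.51 and 33.2% ± 3.28 (SD, n = 3 each, adjusted p = 0.248). The window at 32001 to 33000 on contig564 had 39.4% ± 1.94 and 46.5% ± 2.98 on day 10 (SD, n = 3 each, adjusted p = 0.664). Not all of these windows kept their direction on other days. The contig554 window was 6.15 points higher in 5AZA libraries on day 7 (adjusted p = 0.998). The window at 745001 to 746000 on contig595 was 6.51 points higher on day 10 (adjusted p = 0.664). The day 4 window on contig595 was also lower on day 7 (-4.23 points), and the contig564 window was also higher on day 7 (5.73 points). On day 10 the median window was 0.554 points higher in 5AZA libraries, and of 915 windows with an unadjusted p under 0.05, 891 were higher. On day 6 the direction was the opposite, with a median of -0.192 points and 1161 of 1507 such windows lower. Of such windows, 797 were higher and 373 lower on day 4, 51 higher and 162 lower on day 5, and 214 higher and 180 lower on day 7 (1170, 213 and 394 in all).

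Beside the 0 windows of the quasi-binomial model, limma on log2 ratios also called 0 on each day, with 1273, 323, 1202, 413 and 693 windows at an unadjusted p under 0.05. Limma on unweighted site means called 0 as well, with 319, 224, 1145, 572 and 1781 such windows. Fisher's exact test on reads summed over replicates, which takes no account of the spread between replicates, called 5706, 1642, 3724, 1665 and 4110 windows. On day 6, leaving out 5AZA replicate 1 brought the count from 0 to 1676, of which 1272 were lower and 404 higher in 5AZA libraries.

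Of single CpG sites, 3 passed the threshold among 230443 to 263911 tested per day. They passed on days 6 and 10, when all sites of a day shared the same dispersion. Their p-values therefore do not reflect the spread between replicates at each site. On day 6, position 22959 of contig586 was lower in 5AZA libraries, with 91.8% ± 1.90 in control and 78.3% ± 0.869 (SD, n = 3 each, adjusted p = 0.0311), and position 373647 of contig596-571c was also lower, with 92.1% ± 0.865 and 79.9% ± 0.755 (SD, n = 3 each, adjusted p = 0.0311). On day 10, position 290060 of contig599 was higher in 5AZA libraries, with 53.8% ± 4.91 in control and 80.7% ± 8.05 (SD, n = 3 each, adjusted p = 0.0242). Read depth at these sites was 85 to 182, 112 to 212 and 37 to 80. On the day of the call, the cytosine on the other strand differed by 0.351, -1.59 and 11.7 points at the 3 sites. On the 4 other days, the 5AZA minus control difference was -2.35 to 3.91 points at the contig586 site, -2.44 to 2.74 points at the contig596-571c site and -5.53 to 6.20 points at the contig599 site. No site was called on day 6 when any 1 of the 6 libraries was left out. On day 10, 1 site was called without 5AZA replicate 3 and none without any other library. At an unadjusted p under 0.05 there were 16706, 14065, 19026, 13310 and 19287 sites in the order of the days, and Fisher's exact test on summed reads called 386, 3, 55, 0 and 212.

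With all 30 libraries in one model, no CpG window passed for the treatment. Of 12468 windows, 1638 had an unadjusted p under 0.05, the smallest adjusted p was 0.335, and limma on log2 ratios called none either (1372 at an unadjusted p under 0.05), nor did limma on unweighted site means (407). Differences averaged over the 5 days lay between -1.79 and 1.35 points for 98% of windows. A difference of the same sign on all 5 days was seen in 1298 windows, 960 of them higher and 338 lower in 5AZA libraries. The largest of these was at 456001 to 457000 on contig596-571c, a window with 6 CpG sites, at 35.1% ± 4.14 in control and 39.1% ± 4.85 in 5AZA libraries (SD, n = 15 each, adjusted p = 0.335). In the other direction, the window at 209001 to 210000 on contig568-546-580 had 24.9% ± 4.81 and 21.6% ± 3.88 (SD, n = 15 each, adjusted p = 0.340). Windows can keep 1 sign on all days without a treatment effect, and the windows of a library shift together. The counts of 1298, 960 and 338 were not set against other splits, so they decide nothing about a treatment direction. Among 215000 single sites fitted in the same way, a choice made after seeing the data, none passed, with 14056 at an unadjusted p under 0.05. The test of whether the treatment difference changed with the day called none of 12468 windows, with 509 at an unadjusted p under 0.05 and a smallest adjusted p of 0.916, and limma on unweighted site means called none (856 at an unadjusted p under 0.05).

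The ends of the time course were compared in untreated cultures. Most regions had less methylation on day 10 than on day 4: 74.98% of 12414 CpG windows were lower, with a median difference of -0.607 points. None passed the threshold in the quasi-binomial model (1357 at an unadjusted p under 0.05, of which 1332 lower, and a smallest adjusted p of 0.371), and leaving out control replicate 1 or 3 of day 10 gave 3 or 2 called windows, all lower on day 10. Other measures of the same comparison, chosen after seeing the data, did call regions. With the mean of unweighted site levels per window, limma called 335 of 12536 windows, all lower on day 10. With methylated clusters in place of windows, the quasi-binomial model called 621 of 34592 clusters, all lower on day 10, with a median difference of -3.69 points over all clusters. The day 10 controls also had a CHG level 0.247 points above that of the day 4 controls, and removing the trend on the CHG level took the difference at the sites of 70% or more from -3.54 ± 1.22 to -2.01 ± 1.24 points (SE, n = 3 each). By replicate, the CHG level was 0.707%, 0.515% and 0.488% in the day 4 controls and 0.701%, 0.709% and 1.04% in the day 10 controls. The difference in CHG level thus leaned on replicate 3 of day 10. For 5AZA against control, the cluster test called 0 clusters on days 4, 5, 6 and 7 and 2 on day 10, both higher in 5AZA libraries, and 0 over the 5 days together.

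Non-CG windows rarely reached the 2% needed for a test. At most 2 CHG windows per day and 8 to 23 CHH windows per day were tested and none passed in the quasi-binomial model. No CHG window had an unadjusted p under 0.05, and 1 CHH window on day 6, 2 on day 7 and 1 on day 10 did. Limma on log2 ratios called no CHH window, with 1 at an unadjusted p under 0.05 on day 4 and 1 on day 7. Fisher's exact test on summed reads called 1 CHG window, on day 4, and 6 to 11 CHH windows per day. By pooled level, the highest CHG window of day 7 was at 18001 to 19000 on contig576, with 1.73% ± 0.0863 in control and 1.85% ± 0.108 in 5AZA libraries (SD, n = 3 each). The highest CHH window of that day was at 959001 to 960000 on contig596-571c, with 8.16% ± 2.71 and 7.97% ± 1.18 (SD, n = 3 each). The CHH window at 331001 to 332000 on contig590 had 9.06% ± 4.04 in control and 5.79% ± 0.208 in 5AZA libraries on day 7, and 8.09% ± 1.09 and 5.45% ± 0.836 on day 10 (SD, n = 3 each, adjusted p = 0.0875 on day 10).

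The authors' deposited tables class single CpG sites without a stated adjustment. They list 1223 hypermethylated and 2395 hypomethylated sites on day 4, 1068 and 2072 on day 5, 1012 and 3274 on day 6, 1594 and 1898 on day 7, and 4845 and 584 on day 10, where hypermethylated means higher in 5AZA libraries. In the authors' deposited tables, day 6 had the largest number of hypomethylated and day 10 the largest number of hypermethylated sites. Over the 10 pairs of days, sites classed on both days in the authors' deposited tables had the same direction 581 times and opposite directions 584 times. Only sites with a mean of 5% to 95% can hold arms 10 points apart. Among these, the authors' deposited tables share 580 and 584, where independent lists would share 385 and 457. The numbers for independent lists take all these sites as equally likely to be classed. The spread of a site depends on its level and depth, so a larger overlap does not by itself show a shared effect. Pairs of days differed: days 4 and 6 shared 97 sites in the same and 36 in opposite directions in the authors' deposited tables (48.1 and 33.8 for independent lists), and days 6 and 10 shared 40 and 115 (35.7 and 89.6 for independent lists). A rule of the same form, an unadjusted p under 0.05 in the quasi-binomial model and a difference of at least 10 points, gave 7207, 5154, 7415, 5671 and 9584 sites in the order of the days. Among the other ways to split the 6 libraries of a day into 3 and 3, the largest number was 8347, 9572, 8333, 6533 and 9171; the splits are too few (10) for a share under 0.05.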

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

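Comparisons that use unweighted site means per window, methylated clusters, fewer scaffolds or the sites of 70% or more were chosen after seeing the data, as were leaving out replicates for the interactions and unweighted site means across days. Of 579 alternative values for 59 results, 513 kept their direction and their side of the threshold (on the adjusted p where tests were adjusted together) and 66 did not. A coverage minimum of 10 reads kept all 59. Some of these outcomes were fixed in advance. The exact tests of daily level differences cannot give a p below 0.1, so for these only the direction could change. An added threshold of 10 points cannot raise a count of 0. The numbers kept are therefore no measure of how firm the results are. A minimum of 3 reads was not run, since no listed cytosine has fewer than 5 reads in any library, and limma on log2 ratios was not run for CHG windows, of which at most 2 per day were tested. At single sites of intermediate level, simulated changes of 10 points were rarely called at the depth and number of replicates here. For the changes below, the cause was not tested unless stated.

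Leaving out 1 library gave these ranges for the CpG level difference: -0.133 to 0.426 points on day 4, -0.318 to 0.0856 on day 5 and -0.0566 to 0.280 on day 7. With an unweighted mean of site fractions the day 7 difference was -0.133 points, and the CpG range across days in controls was 0.613 points and passed the adjustment (permutation p = 0.00366, adjusted p = 0.0220). Leaving out 1 replicate number gave 0.657 to 1.16 points for the CpG range across days in controls. It gave -0.0114 to 0.119 points for the CHG and -0.00852 to 0.124 points for the CHH difference over the 5 days. The F of the CHG interaction was 0.597 to 3.48, and that of the CHH interaction was 0.538 to 3.37. At the sites of 70% or more the range was -2.52 to 0.506 points for day 5, -1.49 to 0.411 points over the 5 days and 2.92 to 4.90 points across days in controls.

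Counts of CpG windows past the threshold were 0 to 1 on day 4, 0 to 1676 on day 6 and 0 to 1 on day 10 with 1 library left out; 1676 came without 5AZA replicate 1. CHH windows numbered 0 to 1 on days 5, 6 and 10. Single sites numbered 0 to 1 on day 5, 0 on day 6 (2 with all libraries) and 0 to 1 on day 10. Windows of day 10 against day 4 in controls numbered 0 to 3, with 3 without control replicate 1 of day 10 and 2 without control replicate 3 of day 10. Fewer libraries were fitted in each of these cases.

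Fisher's exact test on summed counts called 5706, 1642, 3724, 1665 and 4110 CpG windows in the order of the days, 1 CHG window on day 4, and 11, 6, 9, 8 and 7 CHH windows; it called 386 single sites on day 4, 3 on day 5, 55 on day 6 and 212 on day 10. It takes the summed reads as independent, which accounts for larger counts by its construction. Without the filter on pooled methylation, 4 CHG windows were called on day 4 and 2 on each of days 6, 7 and 10, and 3, 4, 4 and 3 CHH windows were called on the same days. With 500 bp windows, 1 CHG window was called on day 4, 1 CHH window on day 6 and 1 on day 7. Methylated clusters in place of windows gave 2 on day 10, and 621 for day 10 against day 4 in controls, where limma on unweighted site means gave 335.

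Between the arms of a day, the correlation of the deviations of libraries with the same replicate number was over 0.1 in 3 of 15 pairs (-0.495 to 0.278), and 4 of 15 were most alike with their own number. Between the days of an arm it was over 0.1 in 17 of 60 pairs (-0.501 to 0.677), and 21 of 60 were most alike with their own number. Without pairing, about 1 in 3 would be most alike with their own number. By arm it was 12 of 30 in controls and 9 of 30 in 5AZA libraries. In controls the correlations for replicates 1, 2 and 3 were 0.0928, 0.567 and 0.511 between days 7 and 10. Between days 4 and 10 they were 0.0825, -0.140 and -0.0519. The numbers were not taken to pair the libraries, but pairing of some control cultures across days stays open. The replicate block changed 5 of 52 results: 8 CpG windows on day 6, 1 CHH window on day 7, 0 single sites on day 6 and 0 on day 10 were called, and the CpG range of 0.920 points across days in controls passed the adjustment (permutation p = 0.000780, adjusted p = 0.00468, against 0.0108 and 0.0646 without the block). It changed no other call. For level differences between the arms, daily or over all days, it could change none. The block leaves the difference itself as it was, and its exact test cannot give a p below 0.1.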

Other observations

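All tests in this part were chosen after the results were seen.

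A small number of CHH cytosines had a high share of methylated calls on day 7, the only day with a complete CHH table. Of 3864026 CHH cytosines, 613 had a pooled level of 50% or more, and these lay in 58 windows of 1 kb. The window at 331001 to 332000 on contig590 held 48 of them, the window at 1349001 to 1350000 on contig599 held 28 and the window at 1174001 to 1175000 on contig596-571c held 27. The 613 cytosines had a median depth of 12 reads per library, against 38 for all CHH cytosines. Whether incomplete conversion or mapping made these calls was not tested. Of the CHG cytosines of that day, 14 of 1230209 reached 50%.

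A further 1900 CHH cytosines of day 7 had levels of 10% to 50%. A hypothesis tested on them was that they are placed like the methylated CpG clusters. Of these cytosines 14.4% lay inside clusters, against 2.94% of the 3861513 CHH cytosines under 10% (odds ratio 5.54, Fisher's exact p = 8.34e-102, across cytosines, which are not independent replicates). Of the 613 cytosines of 50% or more, 6.69% lay inside clusters. The placing of the 1900 leaves open some CHH methylation beside methylated CpG sites. Over all listed CHH cytosines, however, the level inside clusters was above that outside in only 7 of 30 libraries. Wrong base calls or sequence variants at such positions were not tested.

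The regular spacing of methylated CpG clusters was set against technical sources. If the placing of CG dinucleotides made it, CpG pairs would be scarce at 90 bp, but there were 0.952 times as many pairs at 90 bp as at 177 bp. Read depth did not follow the spacing, since its correlation at 177 bp minus that at 90 bp was -0.00289. Incomplete conversion inside clusters would raise CHG calls there, and these differed from outside by -0.00658 ± 0.0131 points (SD, n = 30). All 3 were excluded as the source, so the spacing may be biological; a distance near that between nucleosomes is a hypothesis only, as no nucleosome positions were used here, and the design has no group that tests it.

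Libraries with a higher CHG level had a lower level at the CpG sites of 70% or more, with Pearson's r of -0.772 (permutation p = 2e-05, adjusted p = 5e-05) and Spearman's rho of -0.524 (permutation p = 0.00359, adjusted p = 0.00598) over 30 libraries, the p-values adjusted over 5 relations. Without the 2 libraries farthest from the median CHG level, 5AZA replicate 2 of day 4 and control replicate 3 of day 10, r was -0.498 (permutation p = 0.00653) and rho -0.414 (permutation p = 0.0292), so those 2 libraries alone did not make the relation. Treatment with 5AZA was excluded as the whole source, since r was -0.802 (permutation p = 0.000580) and rho -0.786 (permutation p = 0.000820) in the 15 controls, against -0.771 (permutation p = 0.00549) and -0.457 (permutation p = 0.0904) in the 15 5AZA libraries. Base errors that swap both kinds of call equally would give a slope of -0.635 points per point and incomplete conversion alone a slope above 0, but the slope was -6.62 ± 1.03 (SE), and -6.66 ± 0.997 (SE) for deviations from the mean of each day and arm (r of -0.784 and rho of -0.685). What made the libraries differ stays open.

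Control cultures had a lower level at these CpG sites on day 10 than on day 4, by -3.54 ± 1.22 points (SE, n = 3 each, exact p = 0.1). Leaving out any 1 of the 6 libraries left -4.64 to -2.55 points, so no single library made the difference. Part of it may go with the higher CHG level of the day 10 controls: after removal of the CHG trend of the other 24 libraries, -2.01 ± 1.24 points (SE) remained, which keeps this explanation open. Time in culture, acting alike in both arms, also stays open: the treatment by day interaction had a permutation p of 0.146. The 5AZA libraries differed by 2.38 ± 2.67 points (SE, n = 3 each, exact p = 0.7), and by -0.265 points without replicate 2.

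Other splits of the libraries were counted for windows in the quasi-binomial model and for the single sites of each day. They were not counted for methylated clusters, for limma or for single sites over all days. For the daily comparisons and for day 10 against day 4 in controls, the splits are too few (10) for a share under 0.05. The real number of CpG windows was 0 on each day, and the highest of the other splits was 387 on day 5 and 0 on the remaining days. What sets the split of day 5 with 387 windows apart was not tested. For CHG windows the real number was 0 and the highest other 1 on day 5 and 0 otherwise, and for CHH windows it was 0 against 1 on days 4, 5, 6 and 10 and 0 on day 7. For single sites, the real number and the highest other were 0 and 4 on day 4, 0 and 2 on day 5, 2 and 17 on day 6, 0 and 0 on day 7, and 1 and 9 on day 10; 3 of the splits of day 6 and 2 of those of day 10 gave as many sites as the real one, itself included. For windows of day 10 against day 4 in controls, both numbers were 0 in the quasi-binomial model. The clusters and the limma windows called in that comparison were not set against other splits. Over the 5 days the real number was 0, so all 100 within-day splits necessarily gave as many and decide nothing about chance. The highest other gave 3163 windows, and what made that split differ was not tested. For the interaction all 100 splits gave 0, which decides nothing either.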
